A study of Homo sapiens with 4 samples.

How the data were processed

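RNA was measured in 4 libraries of SKOV3, an established human ovarian carcinoma cell line with amplified ERBB2. The 2 wild-type libraries and the 2 cisplatin-resistant libraries were labelled as replicates 1 and 2 of their group. Per the labels' protocols, the resistant cells were derived from wild-type cells by 6 cycles over 5 months, each of 4 hours of cisplatin at rising concentration followed by 3 weeks without the drug. Both kinds of cells were collected untreated during log growth. Per the labels' protocols, polyadenylated RNA was made into libraries with a kit that keeps the strand of the RNA.

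The deposited counts are whole numbers of reads per gene, not normalized. Reads were aligned with STAR 2.5.1a to GRCh38.p7, and HTSeq and DESeq are named without a version, per the submitters' processing notes. The counting settings and the gene annotation are not given in the sources used here. A further deposited table holds a normalized signal, which in every library equals the count divided by a single factor. Those factors were 0.725 and 0.879 for wild-type replicates 1 and 2, and 1.132 and 1.418 for resistant replicates 1 and 2, with the ratio of the tables varying by at most 1.4e-14 over genes with reads. The normalized signal was used only for alternatives.

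The table lists 65988 gene identifiers, of which 56927 are in GENCODE release 29, the annotation used here for positions on GRCh38, gene types and transcript GC content. Identifiers outside the primary assembly of that release held between 0.058% and 0.069% of the counts of a library. Symbols that a spreadsheet had turned into date numbers (25) or that were blank (26744) were replaced by the annotation's name, or left as identifiers.

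A 0 in the deposited counts does not always mean an unexpressed gene. Of the 1808 protein-coding genes whose whole span is covered by other genes in release 29, 1553 (85.9%) are listed at 0 in all libraries, against 1281 of 7195 (17.8%) whose span meets no other gene. The wholly covered genes at 0 include genes that dividing cells need, such as the tubulin TUBA1B, the ribosomal protein RPL32 and the translation factor EIF4A1. The share was 91.8% for the 864 genes covered by opposite-strand genes alone, and 94.5% for the 655 covered genes that share no exonic base with another gene. The mitochondrially encoded genes were also listed at 0, as were many genes that are not wholly covered, HLA-B among them. Of 10683 partly covered protein-coding genes 427 (4.0%) were at 0. Which of the genes at 0 are unexpressed is not known. A gene at 0 in every library was therefore treated as not measured. Named genes over 50% covered by other genes were ATP7A, DDIT4, HIST1H3D, HLA-C, PSMB9, RBBP8, RPA3, RRM2 and SOD2, and their values are less certain, as are those of antisense genes and of genes with near-identical copies.

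Library totals were 43658695 and 53502349 counts for wild-type replicates 1 and 2, and 65259794 and 79592903 for resistant replicates 1 and 2. At these depths 1 CPM (a read count scaled to TMM library size) stands for 42.6 to 83.1 counts. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A group at 0 was given a floor of 3 counts over the group, and folds against it are lower bounds. Groups at 1 to 3 counts have a ratio with a 95% exact binomial (Clopper-Pearson) interval.

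Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM factors (0.976, 0.96, 1.022 and 1.045 in the order above), the default filterByExpr filter (minimum count 10, minimum total 15) and the group as the only term. P-values were adjusted by the Benjamini-Hochberg method, and genes under 0.05 were called. CPM values use TMM-scaled library sizes. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Gene lists (32, of which 30 had at least 5 tested members) were tested with camera from limma 3.58.1, a competitive test of a list against all other tested genes, with a preset correlation of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation and fry. With so few libraries the estimated setting leaves few degrees of freedom, so few lists, families or windows could be called under it. The unfolded protein list had an estimated correlation of 0.006, below the preset value, yet its camera p went from 0.0012 to 0.077. Losing a call under this setting therefore decides little about correlation between genes. The other lists called with the preset had estimated correlations from 0.029 (epithelial genes) to 0.323 (ERBB2 amplicon), all above 0.01. Their p-values with the preset correlation may therefore be too small. Python 3.11.15, pandas 2.3.3, Biopython 1.88 and matplotlib 3.10.9 were used for tables and figures.

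The groups, tests, gene lists, processing alternatives and the rule for named genes were chosen before the data were examined. The rule names the 10 largest rises and 10 largest falls among called protein-coding genes with an official symbol and a mean of at least 5 CPM. It adds 10 fixed genes of platinum handling, repair and ERBB2, and up to 4 members with the lowest adjusted p from each list, or 2 where no member passed. It covers 139 genes, some of which are not reported here. AC069061.2, TUFMP1, CDH3, CDK12, COL1A1, FBLN1 and the members of gene families outside it were named after their values were seen. The treatment of overlapping genes was decided after the values had been seen.

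The test was tried on simulated counts for this comparison, with 18101 genes left after edgeR's filter. They were drawn from the real means, the library sizes and the dispersions that edgeR had fitted. Changes were planted among genes with a mean of at least 1 CPM, in 50 genes at 1.5-fold, 50 at 2-fold and 100 at 4-fold. Such counts follow edgeR's own model, which favours its rates, and do not show recovery at lower levels. EdgeR recovered 40% of genes changed 1.5-fold, 80% of those changed 2-fold and 100% of those changed 4-fold, with 7 false calls (4.2% of calls). DESeq2 1.42.0 recovered 50%, 78% and 100%, with 13 false calls. The real comparison called 45.3% of tested genes, a far larger share than was planted. The adjusted p depends on that share, so these rates need not carry over to the real comparison.

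Alternatives were DESeq2, limma-voom, other size factors, other low-count filters, the replicate number as a block, removal of each library's GC trend, leaving out each replicate, the normalized signal in limma-trend, a test against 1.5-fold, fry, and other window sizes for the chromosome scan. Thinning to the shallowest library and leaving out genes over 50% covered by other genes were added after seeing the data. The labels call the samples biological replicates without saying that they were separate cultures, so p-values measure only the spread between these samples, which may be technical.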

Results

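Gene expression was measured by RNA sequencing in SKOV3 ovarian carcinoma cells and in a cisplatin-resistant line derived from them, with 2 libraries for each. Library totals were 43658695 and 53502349 counts for the wild-type libraries and 65259794 and 79592903 for the resistant libraries, and the resistant libraries together held 1.49 times the counts of the wild-type libraries. Genes with at least 10 reads numbered 17497 and 17838 in the wild-type libraries and 18173 and 18798 in the resistant libraries. Across genes, log2 CPM correlated at 0.984 between the wild-type replicates, at 0.99 between the resistant replicates and at 0.922 to 0.927 between groups, where genes are not independent replicates. Replicates differed beyond sampling noise, with a chi-square over its degrees of freedom of 18.5 for wild-type and 51.9 for resistant cells. Levels below are means ± SD of the 2 libraries of a group (n = 2), in CPM, and log2 changes (± SE) are resistant over wild-type.

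The comparison asks which transcripts differ between cells that survived repeated cisplatin exposure and the cells they came from, both grown without drug. Resistant cells had lower levels of most epithelial, interferon-stimulated and class I antigen presentation genes measured, and higher levels of many DNA replication genes. The keratin KRT5 fell from 82.3 ± 5.03 CPM to no reads, and the keratin KRT7 from 365 ± 47.2 to 3.21 ± 0.0932 CPM. The gelatinase MMP2 rose from 39.1 ± 0.568 to 646 ± 12.4 CPM, and the collagen chain COL6A3 from 0.463 ± 0.076 to 43.6 ± 7.78 CPM. ERBB2, the receptor tyrosine kinase amplified in this line, fell from 5509 ± 368 to 2457 ± 542 CPM.

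Of 18602 genes tested, edgeR's quasi-likelihood test called 4112 higher and 4308 lower in resistant cells at a Benjamini-Hochberg adjusted p under 0.05, 45.3% of those tested. At least 2-fold changes were fitted for 1629 of the higher and 2207 of the lower genes. The median log2 change over all tested genes was 0.003, and the biological coefficient of variation was 13%. The labels describe the same selection for both resistant libraries and do not say that it was repeated. No line grown as long without drug was analysed here, so drug resistance and divergence of the line are not separated.

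Among the 10 largest rises of well-expressed protein-coding genes, the proteoglycan DCN on chromosome 12 (91140484 to 91183123, GRCh38) rose by 8.91 ± 0.39 on the log2 scale, from 0.0567 ± 0.0526 to 26.7 ± 6.87 CPM. SRGN, the core protein of another proteoglycan, rose by 8.41 ± 0.32 and the potassium channel gene KCNJ15 by 7.17 ± 0.45. COL6A3 on chromosome 2 (237324003 to 237414375) rose by 6.56 ± 0.23 and the interleukin-13 decoy receptor IL13RA2 by 6.48 ± 0.24. The interferon-stimulated gene IFI44L rose by 5.67 ± 0.21, the transcription factor gene CREB3L1 by 5.12 ± 0.41 and the transporter gene SLC16A9 from 0.659 ± 0.335 to 18.8 ± 2.2 CPM. NAV3 and the scavenger receptor family gene SCARA3 rose by 4.73 ± 0.33 and 4.65 ± 0.16. Adjusted p-values of these 10 genes in edgeR's quasi-likelihood test ran from 4.25e-09 for SCARA3 to 2.26e-06 for CREB3L1, and each was higher in both resistant libraries. Some of these folds rest on few wild-type counts. KCNJ15 had 0 and 10 counts in wild-type replicates 1 and 2, so its log2 change was 6.31 without replicate 1 and is a lower bound without replicate 2. SRGN (7 and 2 counts) and DCN (4 and 1 counts) had log2 changes of 7.65 and 8.13 without wild-type replicate 2, and rest on 2 and 1 counts without replicate 1. The log2 change of CREB3L1 was 4.44 without wild-type replicate 1 and 6.89 without replicate 2. That of NAV3 was 5.51 without wild-type replicate 1, and that of SLC16A9 was 5.48 without wild-type replicate 2.

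Among the 10 largest falls, 6 genes had no reads in either resistant library. KRT5 on chromosome 12 (52514575 to 52520687) went from 7760 counts in wild-type cells to 0, at least 4130-fold lower. FAM84A was at least 1740-fold lower, the glycosyltransferase gene B3GALNT1 at least 1530-fold lower and TSPYL5 at least 941-fold lower. The organic anion transporter SLCO2B1 was at least 879-fold lower, and CYB5A, which encodes cytochrome b5, at least 496-fold lower. The stanniocalcin gene STC2 had 3 counts in resistant cells against 2678, a ratio of 1420 (counting interval 487 to 6910). GPR27 had 3 against 1810, a ratio of 962 (329 to 4670). The adhesion molecule MCAM fell by 9.47 ± 0.31 on the log2 scale and the mucin MUC5AC, with 3 and 1 counts in resistant replicates 1 and 2, fell by 9.51 ± 0.40. Without either of these libraries the folds of MUC5AC, STC2 and GPR27 rest on at most 3 resistant counts. All 10 passed edgeR's quasi-likelihood test, with adjusted p-values from 1.1e-09 for KRT5 to 6.45e-08 for CYB5A. Over all tested genes, 24 had at least 1 CPM in both wild-type libraries and no reads in resistant cells, and 19 of these are protein-coding. The opposite pattern held for 2 genes, AC069061.2 and TUFMP1, which are named after their values were seen and were at least 292-fold and 178-fold higher.

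**Figure D1:**
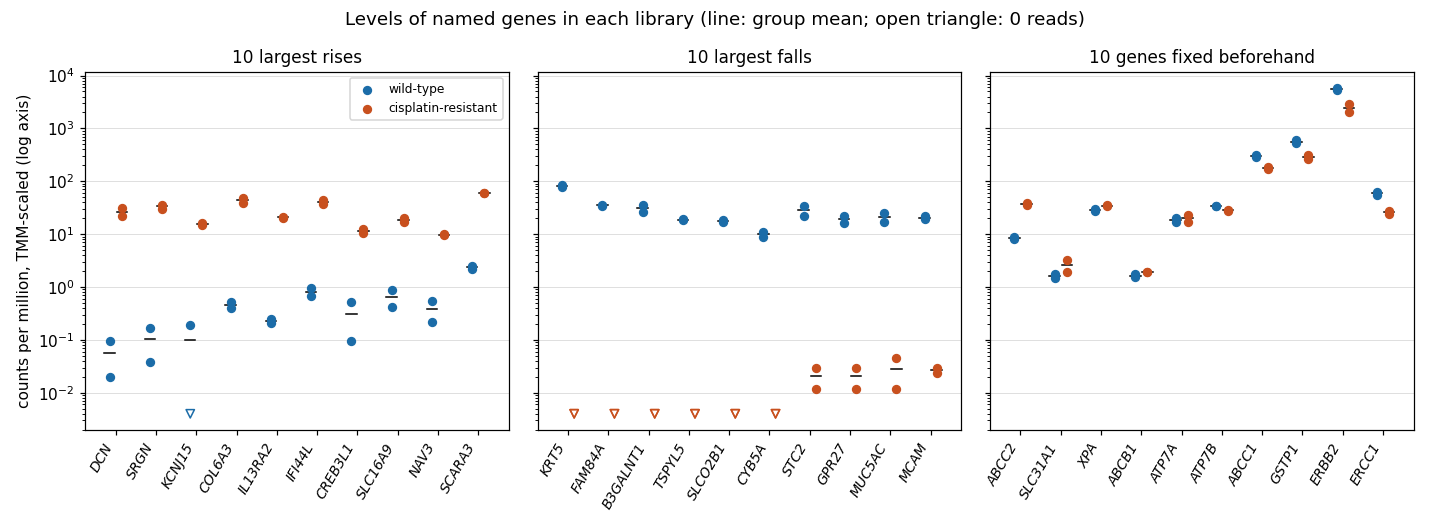
Levels in CPM (log axis) of the 10 largest rises, the 10 largest falls and the 10 genes fixed beforehand, with 1 point per library, a line at each group mean and open triangles for libraries with 0 reads. KRT5 has 82.3 CPM in wild-type cells and no reads in resistant cells, while the levels of ATP7A in the libraries of both groups overlap.

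Among 10 genes fixed for their part in platinum handling, repair or this line's biology, 5 changed, where 45.3% of all tested genes were called. The efflux pump ABCC2 on chromosome 10 (99782640 to 99852594) rose from 8.35 ± 0.511 to 37.0 ± 1.95 CPM, a log2 change of 2.15 ± 0.15. ERCC1, a subunit of the excision repair nuclease, fell from 59.02 ± 5.92 to 26.04 ± 2.39 CPM. The glutathione transferase GSTP1 fell by 0.95 ± 0.12 and the efflux pump ABCC1 by 0.75 ± 0.11 on the log2 scale. ERBB2 on chromosome 17 (39687914 to 39730426) fell by 1.17 ± 0.15. In edgeR's quasi-likelihood test their adjusted p-values ran from 6.83e-07 for ABCC2 to 0.000307 for ABCC1. The copper transporters SLC31A1, ATP7A and ATP7B had log2 changes of 0.64 ± 0.32, 0.10 ± 0.18 and -0.27 ± 0.13, with edgeR adjusted p-values of 0.125, 0.663 and 0.102. The drug pump ABCB1 (0.24 ± 0.29, edgeR adjusted p = 0.539) and the damage recognition gene XPA (0.27 ± 0.13, edgeR adjusted p = 0.101) did not pass either. Nearly the whole span of ATP7A is covered by another gene, so its value is less certain. SLC31A1 had 1.63 ± 0.215 CPM in wild-type and 2.55 ± 0.908 CPM in resistant cells. Leaving out resistant replicate 2 gave it a call (0.98, edgeR adjusted p = 0.028), while the log2 fold change of SLC31A1 was 0.24 without resistant replicate 1 (edgeR adjusted p = 0.69), the ends of the range over its alternatives.

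Transporters of platinum and copper were mostly lower where they changed. Of 23 tested, 10 fell and 2 rose, or 10 and 3 adjusted over the list alone. The organic cation transporter SLC22A3 fell from 11.9 ± 0.812 to 0.0977 ± 0.117 CPM, with 1 and 15 counts in resistant replicates 1 and 2. Its log2 change was -6.02 without resistant replicate 1, and rests on 1 count without replicate 2. Its neighbour SLC22A2 fell by 2.12 ± 0.14 and the copper chaperone CCS fell by 1.37 ± 0.16. SLC22A2, SLC22A3 and CCS lie in chromosome windows that were lower as a whole, described below. As a set the list was not called (median log2 change -0.25, camera adjusted p = 0.13). Of the metallothioneins, which bind metals, only MT2A was tested, and it fell from 149 ± 38 to 64.6 ± 11.6 CPM. Glutathione and NRF2 target genes moved both ways, with 9 of 31 higher and 11 lower, or 9 and 12 adjusted over the list alone. The heme oxygenase HMOX1 rose from 23.1 ± 0.403 to 129 ± 28.7 CPM, and the microsomal transferase MGST1 rose by 1.26 ± 0.12. The list's median was -0.22, its mean 0.02 and its camera direction up, with an adjusted p of 0.88.

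Repair genes changed in both directions, where 45.3% of all tested genes were called. In nucleotide excision repair, which removes platinum adducts, 6 of 32 genes rose and 8 fell, also when adjusted over the list alone. Its median was -0.02 and its mean -0.03 while the camera direction was up, with an adjusted p of 0.91. The damage sensor DDB2 rose by 1.10 ± 0.13 and its partner DDB1 fell by 0.99 ± 0.12. In homologous recombination and the Fanconi anemia pathway, 14 of 32 genes rose and 2 fell, the same numbers adjusted over the list alone. BRCA1 rose from 89.1 ± 3.53 to 178 ± 26.4 CPM and its helicase partner BRIP1 from 52.8 ± 4.47 to 109 ± 1.65 CPM, while FANCF fell by 1.47 ± 0.15. The set missed the threshold (camera adjusted p = 0.055). In the set test of list homologous recombination and Fanconi anemia, adjusted p ranged over the alternatives from 0.012, with genes over 50% covered by other genes left out, to 0.43 with an estimated correlation. Mismatch repair had 2 of 8 genes higher (EXO1 and PMS2) and 2 lower (MLH3 and MSH3), the same adjusted over the list alone, with a camera adjusted p of 0.87. Translesion synthesis had 6 of 14 higher and 1 lower, or 6 and 2 adjusted over the list alone, with a camera adjusted p of 0.38. The ubiquitin ligase RAD18 rose by 0.82 ± 0.13 and the polymerase POLQ by 0.59 ± 0.11.

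Target genes of p53 and regulators of apoptosis were not called as sets by camera. Of 26 p53 targets 6 rose and 9 fell, or 7 and 9 adjusted over the list alone (camera adjusted p = 0.56), and fry, which does not compare a list with other genes, called them lower (adjusted p = 0.021). The growth factor GDF15 fell from 55.1 ± 13.1 to 5.16 ± 0.84 CPM, PHLDA3 fell by 1.95 ± 0.14 and the cyclin CCNG1 fell by 1.30 ± 0.12. Anti-apoptotic factors had 3 of 14 higher and 3 lower, the same adjusted over the list alone (camera adjusted p = 0.69). Of these, BIRC7 rose from 10.4 ± 3.73 to 64.2 ± 11.9 CPM, and BIRC3 fell by 1.58 ± 0.17. Pro-apoptotic factors had 7 of 24 higher and 7 lower, also when adjusted over the list alone. Their median was -0.04 and their mean -0.06 while the camera direction was up (adjusted p = 0.93). Cytochrome c (CYCS) rose by 1.00 ± 0.12 and the caspase gene CASP10 fell by 1.16 ± 0.14.

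Epithelial genes were lower as a set. Of 33 tested, 22 fell and 1 rose, the same numbers adjusted over the list alone, and the median log2 change was -1.05. KRT7 fell by 6.83 ± 0.16, E-cadherin (CDH1) fell by 5.51 ± 0.25 and the protease inhibitor SPINT2 fell by 4.12 ± 0.14. The rise was in the P-cadherin gene CDH3 (0.94). The camera adjusted p was 6.5e-18, and the call was lost with adjusted p = 0.43 with an estimated correlation. Few lists could pass under that setting with so few libraries. Mesenchymal genes did not move together: 12 of 34 rose and 12 fell, or 13 and 12 adjusted over the list alone (camera adjusted p = 0.57). MMP2 rose by 4.05 ± 0.12 and the repressor of E-cadherin SNAI2 rose from 20.1 ± 0.408 to 157 ± 11 CPM, while the smooth muscle protein TAGLN fell by 2.53 ± 0.13. That list's median was 0.1 and its mean -0.05, with the camera direction up. Stem cell associated genes had 4 of 15 higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.56). The intermediate filament gene NES rose by 1.38 ± 0.13 and POU5F1 fell by 0.97 ± 0.14.

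Interferon-stimulated genes were lower as a set, with 23 of 31 lower and 4 higher, the same numbers adjusted over the list alone, and a median log2 change of -0.89. IFI27 fell from 97.2 ± 0.525 to 22.4 ± 2.08 CPM and EPSTI1 from 17.6 ± 1.28 to 3.28 ± 0.501 CPM. IFI44 went the other way, from 7.995 ± 0.15 to 79.9 ± 0.696 CPM, as did its neighbour IFI44L. The camera adjusted p was 0.0066, with adjusted p = 0.43 with an estimated correlation, and in the set test of list interferon-stimulated genes adjusted p ranged from 0.00013 in limma-voom to that value, with 0.072 where a mean of at least 5 CPM was required. Of the 9 members not tested, 8, IFIT1 among them, lie wholly within other genes and are listed at 0, as are the transporter genes TAP1 and TAP2. Class I antigen presentation genes were lower, with 12 of 17 lower and 0 higher, the same adjusted over the list alone, a median of -0.85 and a camera adjusted p of 1e-05 (adjusted p = 0.43 with an estimated correlation). The class I transactivator NLRC5 fell from 181 ± 8.86 to 60.6 ± 6.72 CPM, and the immunoproteasome subunit PSMB9, over 50% covered by other genes, fell by 2.52 ± 0.14. NF-kB target cytokines and regulators had 6 of 26 higher and 11 lower, or 6 and 12 adjusted over the list alone (camera adjusted p = 0.56). Interleukin 6 (IL6) rose from 4.96 ± 0.519 to 23.1 ± 1.15 CPM and interleukin 1 beta (IL1B) fell from 12.1 ± 1.26 to 2.45 ± 0.0603 CPM.

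Cell cycle genes were higher by modest amounts. In S phase and DNA replication 28 of 41 genes rose and 2 fell, the same adjusted over the list alone, with a median log2 change of 0.41. The clamp loader subunit RFC5 rose by 0.93 ± 0.11 and the replication regulator DTL by 0.82 ± 0.11. Its camera adjusted p was 0.0015, with adjusted p = 0.43 with an estimated correlation. In G2/M and mitosis 18 of 35 rose and 2 fell, or 19 and 3 adjusted over the list alone, with a median of 0.34 and a camera adjusted p of 0.0022 (adjusted p = 0.43 with an estimated correlation). The cytokinesis gene ANLN rose from 231 ± 13.6 to 641 ± 70.2 CPM and the checkpoint kinase BUB1 from 54.8 ± 0.434 to 136 ± 7.17 CPM. Replication-dependent histones, whose messages mostly lack a poly(A) tail, had 8 of 12 tested genes higher and 0 lower, or 9 and 0 adjusted over the list alone, with a median of 0.75 (camera adjusted p = 0.055). HIST2H2BE rose from 10.6 ± 0.0123 to 16.6 ± 1.65 CPM.

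Genes of glycolysis and hypoxia, of cholesterol synthesis and of the unfolded protein response were lower as sets. In glycolysis and the hypoxia response 21 of 33 genes fell and 3 rose, the same adjusted over the list alone, with a median of -0.5 and a camera adjusted p of 0.00019 (adjusted p = 0.45 with an estimated correlation). The glycolytic enzyme GPI fell from 275 ± 10.3 to 101 ± 7.87 CPM and the carbonic anhydrase CA12 from 622 ± 3.13 to 249 ± 18.5 CPM. In cholesterol synthesis 13 of 24 fell and 2 rose, or 13 and 3 adjusted over the list alone, with a median of -0.52 and a camera adjusted p of 0.00054 (adjusted p = 0.43 with an estimated correlation). Squalene synthase (FDFT1) fell by 1.63 ± 0.11. In the unfolded protein and integrated stress response 17 of 30 fell and 2 rose, the same adjusted over the list alone, with a median of -0.39 and a camera adjusted p of 0.0047 (adjusted p = 0.43 with an estimated correlation). Besides STC2, HERPUD1 fell by 0.97 ± 0.11 and CEBPB fell by 1.30 ± 0.16. The nuclear-encoded respiratory chain had 2 of 37 higher and 9 lower, or 2 and 8 adjusted over the list alone (camera adjusted p = 0.63), with NDUFA4 higher by 1.37 ± 0.11. The 15 mitochondrially encoded genes were listed at 0 in every library and not tested.

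**Figure D2:**
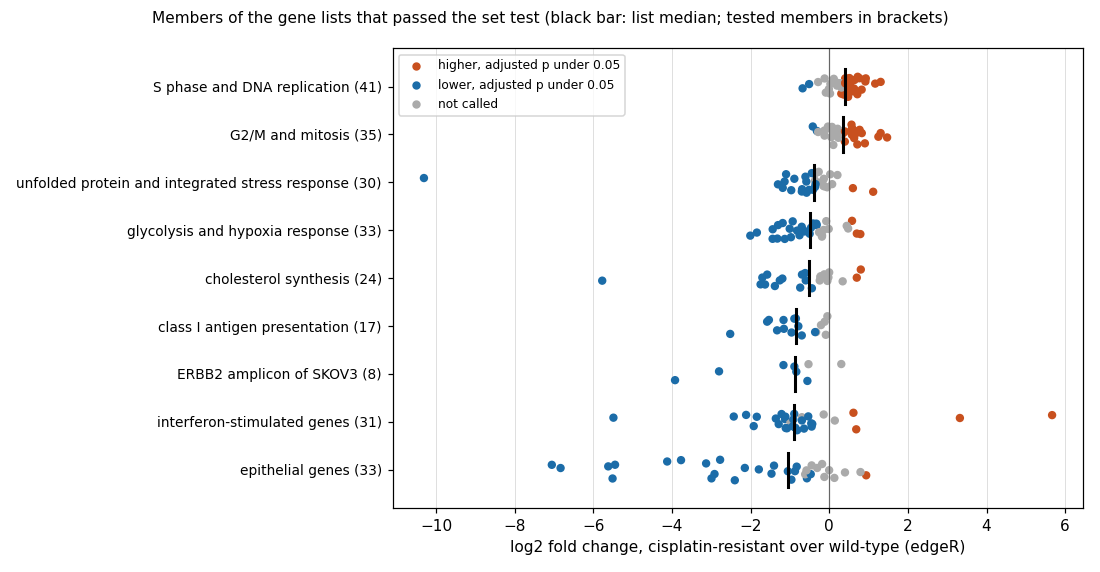
Log2 fold changes, resistant over wild-type, of the tested members of the 9 gene lists that passed camera with the preset correlation. There is 1 point per gene and a black bar at each list's median. None of these lists passed with an estimated correlation. The epithelial list has the lowest median (-1.05) and the S phase list the highest (0.41), while IFI44L stands at 5.67 among interferon-stimulated genes that are mostly below 0 and STC2, farthest to the left, rests on 3 counts in resistant cells.

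Genes around ERBB2, listed beforehand as amplified with it in this line, were lower as a set. Of these, 6 of 8 were lower and 0 higher, or 7 and 1 adjusted over the list alone. Their amplification was not checked, since DNA copy number was not analysed here. The adaptor GRB7 fell from 229 ± 15.9 to 15.1 ± 1.43 CPM, PNMT fell by 2.80 ± 0.25 and STARD3 fell by 0.89 ± 0.12, while CDK12 had a log2 change of 0.31 and did not pass. The median was -0.86 and the camera adjusted p 0.00016 (adjusted p = 0.43 with an estimated correlation). Of 33 receptor tyrosine kinases and ligands tested 10 rose and 8 fell, the same adjusted over the list alone (camera adjusted p = 0.88). The receptor MET rose from 154.5 ± 7.58 to 396 ± 74 CPM, ERBB4 fell by 2.56 ± 0.19 and the ligand PDGFB, with 1 and 3 counts in resistant replicates 1 and 2 and resting on 1 count without replicate 2, fell by 7.95 ± 0.41. TGF-beta and BMP response genes had 11 of 24 higher and 8 lower, or 12 and 8 adjusted over the list alone (camera adjusted p = 0.069). PMEPA1 rose by 2.06 ± 0.11 and the ligand BMP4 from 0.613 ± 0.0698 to 4.45 ± 0.44 CPM. Immediate early and heat shock genes had 5 of 21 higher and 5 lower, the same adjusted over the list alone (median -0.03, mean 0.08, camera direction up, adjusted p = 0.91), with FOSL1 higher by 1.69 ± 0.15 and FOS lower, at 17.01 ± 5.96 and 4.27 ± 0.25 CPM.

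Markers of other cell types were not called as sets by camera. Leukocyte markers had 3 of 8 tested genes lower and 0 higher, the same adjusted over the list alone, with a median of -1.36 and a mean of -1.19 (camera adjusted p = 0.56), and the most abundant of these 3, LCP1, fell from 10.9 ± 1.39 to 5.31 ± 0.751 CPM. Endothelial markers had 1 of 10 higher and 3 lower, also when adjusted over the list alone, with a median of -0.4 (camera adjusted p = 0.66), and with PECAM1 falling from 8.94 ± 1.81 to 0.81 ± 0.0627 CPM. Fibroblast markers had 3 of 9 higher (DCN, LUM and COL1A1) and 3 lower (COL14A1, COL1A2 and FBLN1), the same adjusted over the list alone, with a median of -0.38, a mean of 0.35 and the camera direction down (adjusted p = 0.91). Mullerian and ovarian carcinoma markers had 2 of 11 higher and 4 lower, the same adjusted over the list alone, with a median of 0.12, a mean of -0.62 and the camera direction down (adjusted p = 0.43). The estrogen receptor ESR1 fell from 93 ± 6.17 to 23.1 ± 3.14 CPM and SOX17 fell by 1.40 ± 0.16.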

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

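Thinning, and leaving out genes over 50% covered by other genes, were chosen after the result was seen. Removing the GC trend was planned for genes and lists, and was added for chromosome windows once these had been seen, with its bounds set before its own outcome. The number of genes higher in resistant cells ranged from 2971 with a mean of at least 5 CPM to 4942 with total counts only, apart from leaving out libraries. The number of genes lower in resistant cells was 3003 and 3767 under these settings, 4131 in DESeq2 (3877 higher) and 4879 with the replicate block (4767 higher). Replicate numbers did not pair the samples (correlation of deviations 0.08). With a mean of at least 5 CPM, which tests fewer genes, there were 633 genes at least 2-fold higher and 986 genes at least 2-fold lower. Thinned libraries gave 4063 higher and 4239 lower, and leaving out covered genes, which also tests fewer, gave 3838 and 3873. Leave-one-out fits gave 3330 to 4022 higher and 3417 to 4159 lower; the lone library was assumed to vary like the other group. Lists higher, 2 as reported, were 4 in limma-voom, 4 with no low-count filter, 4 in fry, 4 without covered genes, and 2 to 4 without a replicate in turn (4 without resistant replicate 2). Lists lower were 6 to 10 apart from the estimated correlation, with which 0 lists were higher and 0 lower by camera. Beyond camera's 9 lists, fry called platinum and copper transport, p53 targets and NF-kB targets lower, and TGF-beta response and histones higher. Chromosome windows of 20 Mb gave 14 higher and 12 lower, an estimated correlation 0 and 0, and removing the GC trend 17 higher and 19 lower. Except where fewer genes were tested, the cause was not tested. No named gene's called direction reversed under these alternatives. Without resistant replicate 1 calls were lost for ITGA6 (0.26), HIST4H4 (1.35), WT1 (1.16), the log2 fold change of CORO1A (-1.34) and the log2 fold change of CD4 (-3.45). Without resistant replicate 2 they were lost for HIST1H3D (3.23) and CD4 (-3.15). ITGA6 also lost its call in DESeq2 and with the normalized signal at a pseudocount of 0.1 or with no filter, and MAD2L2 with the GC trend removed (-0.19). XPA gained a call with total counts only and with the replicate block, ATP7B with the replicate block and SLC31A1 without resistant replicate 2. Depth limits genes near the floor of 3 counts.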

Other observations

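The tests of ERBB2 rank and gene overlap, both tests on IFI44 and the scan of gene families were chosen after the result was seen. The GC and odd-even tests of chromosome windows and the test of neighbours of genes without reads were added once those patterns had been seen, with their bounds set before their own outcomes.

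Cadherins were the gene family with the lowest p among 172 families of at least 10 tested protein-coding genes sharing a symbol stem. Of 15 tested, 9 were lower and 3 higher (median log2 change -1.04, camera adjusted p = 4.5e-06, adjusted p = 1 with an estimated correlation). CDH16 fell from 334.6 ± 30.1 to 18.6 ± 0.0815 CPM (SD over 2 libraries) and CDH13 from 48.5 ± 6.97 to 1.05 ± 0.12 CPM. CDH11 had 454 counts in wild-type cells and 0 in resistant cells, at least 241-fold lower. N-cadherin (CDH2) fell by 0.78 ± 0.13 on the log2 scale, while CDH18 rose by 0.72 ± 0.14. Protocadherins followed (5 of 10 lower, 2 higher, camera adjusted p = 0.002, adjusted p = 1 with an estimated correlation), with PCDH9 falling from 43.3 ± 1.39 to 2.49 ± 0.171 CPM.

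Keratins split by gene. Of 14 tested, 6 were lower and 2 higher (camera adjusted p = 0.008, adjusted p = 1 with an estimated correlation). KRT15 rose from 2.4 ± 0.511 to 13 ± 1.22 CPM and KRT17 from 3.69 ± 0.733 to 8.22 ± 0.551 CPM. KRT80 (228 ± 3.5 and 243 ± 1.54 CPM) and KRT19 (144 ± 13 and 144 ± 13.5 CPM) did not pass edgeR's test.

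Neighbouring genes changed together: of 298 windows of 10 Mb, 28 were higher and 19 lower by camera with the preset correlation, and 0 with an estimated correlation. On chromosome 11 from 70 to 80 Mb 62 of 99 tested genes were lower and 5 higher (median -0.66). On chromosome 7 from 20 to 30 Mb 36 of 62 were higher and 4 lower (median 0.88). Chromosomes 7 and 12 held 7 and 8 of the higher windows, and chromosome 11 held 6 lower and 1 higher. SLC22A2, SLC22A3, CCS, GSTP1, DDB1 and ERCC1 lie in lower windows, on chromosomes 6, 11 and 19. PMS2, IL6, CYCS, NDUFA4, ANLN and MET lie in higher windows on chromosome 7. Further examples in higher windows are DCN, NAV3, RFC5, SCARA3, SNAI2, BUB1, IFI44 and IFI44L. In lower windows they are MCAM, TAGLN, SLCO2B1, FAM84A, GPI and SPINT2, and neither list is complete. Changes of these genes are not separated from those of their regions. Chance placement is argued against, since 0 of 100 shuffles of gene positions called as many windows and the highest called 1. A GC trend as the whole cause is argued against as well, since 63.8% of the called windows (30 of 47) kept their call and direction with it removed, although the others did not and window change correlated with window GC at a Spearman coefficient of -0.4, so GC may account for part. Windows called from odd-position genes had the same sign in even-position genes in 100% of 23 cases, which any regional cause would give, so gains and losses of chromosome segments stay open, and DNA copy number was not analysed here.

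Of the 24 genes with reads in wild-type cells and none in resistant cells, KRT5 had the highest wild-type level. Loss of whole segments is argued against by the pairs of such a gene and an expressed neighbour within 1 Mb. In 0.63% of these pairs (2 of 319, 95% interval 0.08 to 2.25) the neighbour also lacked reads. Both are the same overlapping genes counted from each side. Pairs that share genes are not independent, so the interval is approximate. Reads dropped at overlapping genes are argued against for the 13 that meet no other gene and stay open for the other 11, of which 2 are over 50% covered (odds ratio 0.43 against genes without overlap, exact interval 0.17 to 1). Resistant libraries from a line without ERBB2 amplification are argued against by the percentile of ERBB2 among tested genes, at least 99.9 in both. The level of ERBB2 had been seen before this bound was set. Another line with high ERBB2, or a mixture, would meet it too. Silencing or small deletions of single genes may remain, and neither was tested.

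IFI44 and IFI44L were higher while most interferon-stimulated genes were lower. A stronger general interferon response is argued against by the class I antigen presentation genes, which interferon induces. Their median log2 change was -0.85, with 12 of 17 lower and 0 higher. That list had already been seen when the bound was set, and the class I transactivator NLRC5 fell too, so this is no independent test. A local change of this chromosome 1 segment stays open. The other 4 tested genes within 0.5 Mb had a median log2 change at percentile 99.94 of runs of as many genes. All 4 have under 1 CPM in wild-type cells and passed the low-count filter mainly through resistant reads. That favours a rise, so this test decides nothing. The window from 70 to 80 Mb that holds IFI44 and IFI44L was called higher by camera with the preset correlation (median log2 change 0.58, adjusted p = 0.031). It was not called with an estimated correlation. Of its 42 tested genes, which include both, 21 were higher and 6 lower. A local change would give such a window, but so would other regional causes.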
